A study of Brassica napus with 24 samples.

How the data were processed

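Leaf 3 of 24 Brassica napus plants, 3 per group in 8 groups of 2 cultivars and 4 treatments, was profiled on Agilent single-colour arrays. Per the labels' protocols, seedlings were grown in nutrient solution for 28 days at 2 mM N before the 4 days of treatment, total RNA was extracted from frozen leaf tissue, and Cy3-labelled cRNA was made with a low input labelling kit. Each array had 62274 spots, 60955 of them gene probes of 60 nucleotides. Per the file headers, the images were read with Feature Extraction 10.5.1.1 under protocol GE1_105_Dec08, whereas the submitters' processing notes give version 10.1. The deposited processed signal is a fluorescence intensity on a linear scale, per the file headers with the background subtracted and spatial trends removed within each array, and not scaled between arrays. The authors also deposited a matrix of intensity values with 59577 features for the 24 samples, whose method is not recorded. Its column medians all lay between 353.8 and 355.1, its lowest value was 3.91, and 0 of its feature names match a probe name, so its values were used only on their own features.

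Scaled values were log2 of the processed signal minus the log2 of the array's 75th percentile. Control spots were left out, and spots that the scanner software marked as non-uniform or as population outliers were treated as missing (9 to 469 per array). Only 1 spot was saturated over all arrays. A probe was tested when it lay well above background in every replicate of at least 1 group, which kept 49874 probes; 37005 lay above background on all arrays. Linear models with 1 mean per group were fitted to the 24 arrays with limma 3.58.1 in R 4.3.3, with a moderated variance, and 12 contrasts were tested two-sided with Benjamini-Hochberg adjustment per contrast at 0.05. These were each of the 3 inducers against control in each cultivar, the cultivar difference of each response (Capitol minus Apex), Capitol against Apex in controls, and N starvation against shading and against detachment over both cultivars. Files were read with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and Biopython 1.88, and figures drawn with matplotlib 3.10.9. The groups of 3 plants and the 7 slides, read in 3 scans, limit the precision. Slides held arrays of several groups, so a fit with the slide as a block could be had for each comparison. Values within slides could be had for 5 of the 6 treatment comparisons, and none were computed for the others. The layout was not balanced. Slide 1, the only slide of scan 1, held Apex shaded replicate 2, Apex detached replicate 1 and Capitol shaded replicates 1 and 2. It held no control and no N-starved array, so these arrays share neither slide nor scan with any control. Slide 5 held no control either. Its arrays were Apex N-starved replicate 2, Apex detached replicate 3, Capitol N-starved replicate 1 and Capitol detached replicate 2.

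The contrasts, the test, the filter, the gene lists, the rule for named items and most alternatives were fixed before the data were examined. The gene lists, the key genes and the markers of other cell types could not be matched, because neither the files nor the reference pair the probes with gene names. In their place, 72 classes of conserved peptide signatures were written and searched in the 3 forward reading frames of the probes. They were written after the files had been opened and widened on the number of matches alone, before any signal was compared. A class was kept with at least 5 matching probes and at most 20% as many matches in the reverse frames. This held for 16 classes, with 245 forward and 5 reverse matches, and 15 of them had at least 5 tested probes. A signature points to a protein family, not to a gene. Classes were tested with limma's camera (preset correlation 0.01), adjusted over 90 tests for the treatments, 45 for the cultivar differences and 45 for the other contrasts. Camera called 25, 17 and 2 of these; with an estimated correlation it called 0 in each family. Fry was run as well. A cultivar score placed each array between N-starved Apex (0) and N-starved Capitol (1) over 179 probes that differ by more than 4 on the log2 scale between those groups, and slopes placed each array on the mean response of the other cultivar; both were chosen after the arrays had been seen. The named items are, per contrast, up to 2 probes that rose and 2 that fell most with non-overlapping replicates (printed by identifier), and the class members with the largest changes. For a probe above background on 0 arrays of a group, the fold is a lower bound, taken against the lowest signal still well above background on each array (or the probe's own signal, where higher), and is written as "at least". The bound makes no allowance for the slide, and was left out where the fit with a slide block gave a smaller difference, a choice made after the values were seen. For a probe above background on some arrays of a group only, the size of the fitted difference rests on values at the scanner's floor and is no bound; for the probes printed by identifier it is left out. Shares of calls common to comparisons were set against independent lists and against 20 simulations of unchanged groups that share the controls. The simulated probes were drawn independently of each other and without slides. The spread of the simulated values is therefore narrower than that of real arrays, whose probes vary together.

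The fit was tested on simulated data with 100 probes changed 2-fold and 100 changed 4-fold among 49874. For N starvation against control in Apex 11% and 62% were recovered, with 6 false calls; for the cultivar difference in the N starvation response 1% and 31%, with 4 false calls; for N starvation against shading 37% and 83%, with 8 false calls. In each of these contrasts camera called a shifted set of 10 probes and did not call an unshifted set, at an unadjusted p. The simulated probes were independent, so this does not test the preset correlation. Alternatives were quantile normalization, normexp background correction with an offset of 50, no filter or a filter on all arrays, the authors' matrix, a trended robust variance, a 2-fold criterion, blocks for replicate number, slide and scan, only the compared groups in the fit, array weights, leaving out each array, leaving out Apex shaded replicate 1, and leaving out 3 arrays with unusual signal. Gene set tests on all probes of a list gene, and the matrix on the same probes, could not be run.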

Results

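Transcript levels were measured in leaf 3 of hydroponically grown winter oilseed rape (Brassica napus) after 4 days of a senescence-inducing treatment. Cultivar Apex is classed as N-efficient and cultivar Capitol as N-inefficient. In each cultivar 3 plants were controls at 2 mM N, 3 plants were starved at 0.1 mM N, 3 plants had leaf 3 shaded, and 3 plants had leaf 3 detached and kept in deionised water. Each of the 24 plants gave 1 single-colour array, so the 8 groups held 3 biological replicates each, and this number limits the precision. The series asks which transcripts change with N starvation, how far shading and detachment change the same ones, and whether the cultivars respond differently. The 75th percentile of signal per array ranged from 485 to 2371 scanner units. The dimmest arrays were Capitol detached replicate 1 at 485 and Apex shaded replicate 3 at 557, and the next one stood at 1054. Between 68.5% and 85.4% of the gene probes lay well above background, except in Capitol shaded replicate 2, where 97.9% did. The files pair no probe with a gene, so probes were grouped by conserved peptides in their translated sequences: 15 classes held between 6 and 34 probes.

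Arrays of 1 group resembled each other more than arrays of different groups. Across probes, which are not independent replicates, the correlation had a median of 0.963 over the 24 pairs within groups (0.846 to 0.986) and of 0.907 over the 252 pairs between groups (0.765 to 0.964). The first principal component held 23.1% of the variance and the second 16.5%. Apex shaded replicate 1 lay beyond the Apex controls, on the side away from the other shaded Apex leaves, at −182.6 on component 1 against −151.6, −121.6 and −139.4 for the controls. Apex shaded replicates 2 and 3 lay at 46.5 and 37.0. Over the probes that changed with shading in Capitol, replicate 1 followed that response with a slope of −0.157, against 0.835 and 0.665 for replicates 2 and 3. For that reason the main results of shading in Apex are given with and without replicate 1; values within slide 2 and with a slide block include it. All 24 arrays share 1 estimate of the spread, so this array also widened the test of every other comparison, and counts without it follow. Among the Capitol controls, replicate 1 lay at −29.8 on component 1, towards the treated Capitol arrays, against −111.5 and −107.5 for replicates 2 and 3. That control was kept, and it enters each Capitol comparison with control, the cultivar differences and the comparison of the controls.

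**Figure D1:**
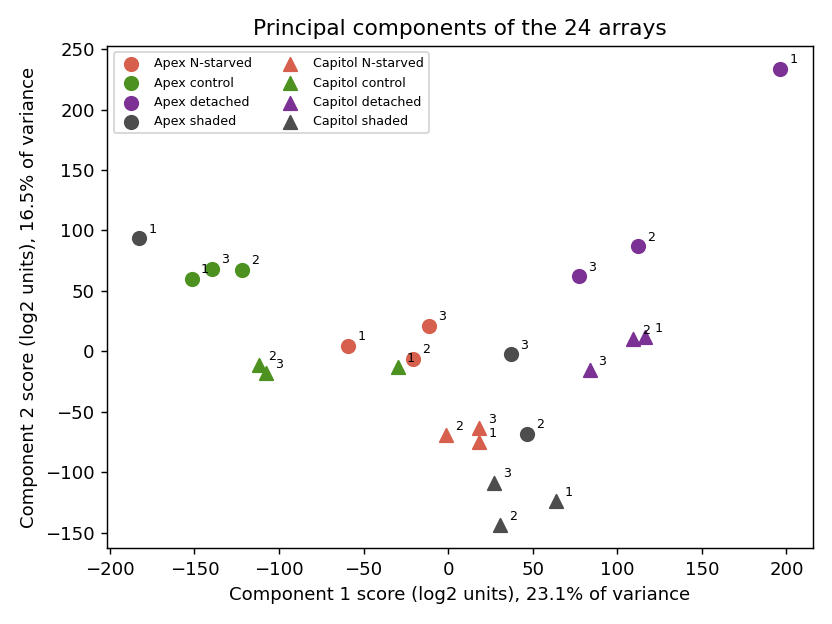
Scores of the 24 arrays on component 1 (23.1% of the variance, horizontal) and component 2 (16.5%, vertical), in log2 units; each point is 1 array, coloured by treatment and shaped by cultivar. Apex shaded replicate 1, at −182.6 on component 1, lies beyond the Apex controls, away from the other shaded Apex arrays.

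N starvation against control in Apex asked what low N changed in leaf 3 of the N-efficient cultivar. Transcripts with signatures of the photosynthetic apparatus were lower. The 15 probes with a chlorophyll a/b-binding signature, found in antenna proteins of the photosystems, averaged −0.96 ± 0.20 relative to control on the log2 scale (SD, n = 3). Here and below, such an average is the mean over the 3 arrays of the median of the class probes in each array. It can differ from the class median, which is taken over the fitted changes of the probes. Of the 15 antenna probes 0 lay above control. The 10 probes with a Rubisco small subunit signature averaged −1.35 ± 0.25. Probes with a NAC signature, a transcription factor family, were higher by 0.62 ± 0.12. As classes, antenna probes fell by a median of 0.88 (camera adjusted p = 1.99e-05, and adjusted p = 0.869 with an estimated correlation) and Rubisco small subunit probes by 1.34 (adjusted p = 1.02e-05, and adjusted p = 0.869 estimated). NAC probes rose by a median of 0.78 (adjusted p = 0.0125, and adjusted p = 0.897 estimated), with 17 of 21 above control. WRKY probes, another transcription factor family, rose by 0.41 (adjusted p = 0.0355, and adjusted p = 0.897 estimated), with 13 of 16 above control. Among single members, limma called 0 of 15 antenna probes and 0 of 10 Rubisco probes, and 8 Rubisco probes fell when adjusted over the list alone. A NAC probe with the peptide WVLCRIY rose by 2.2 (SE 0.45, adjusted p = 0.0107), a cytochrome P450 probe with PLSFRPERF rose by 3.68 (SE 0.81, adjusted p = 0.0166), and an R2R3 MYB probe with LPGRTDNEV fell by 3.62 (SE 0.76, adjusted p = 0.012).

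Across the 49874 probes tested for N starvation against control in Apex, 759 rose and 1167 fell, 1926 in all, of which 1682 changed at least 2-fold. Probe BrsNa0101049 was at least 16.5-fold higher and BrsNa0283312 at least 39.8-fold higher than in control leaves, where 0 of 3 arrays measured them. BrsNa0163873 was at least 119-fold lower, and BrsNa0185755 fell, with 1 of 3 N-starved arrays above background. Within the slides that held both groups, antenna probes differed by −0.66 and −1.21, Rubisco probes by −1.06 and −1.68, NAC probes by 0.72 and 0.76 and WRKY probes by 0.33 and 0.48. A block for the slide gave 957 calls, which did not include BrsNa0101049 or the R2R3 MYB probe (−3.34 with the block). The class medians were then −0.72 (adjusted p = 0.000464), −1.07 (adjusted p = 0.000202), 0.70 (adjusted p = 0.00363) and, for WRKY, 0.27, which was no longer called (adjusted p = 0.119), nor was it with the scan as a block (0.31, adjusted p = 0.0707). Under quantile normalization the antenna class differed by −0.26 and was not called (adjusted p = 0.0787). Leaving out 1 array changed these calls. The count was 1064, 696 and 491 without N-starved replicate 1, 2 or 3, and 864, 890 and 668 without control replicate 1, 2 or 3. It was 5772 without Apex shaded replicate 1, which is in neither group. The NAC call ended without control replicate 3 (0.83, adjusted p = 0.052). The WRKY call ended without N-starved replicate 1 (0.43, adjusted p = 0.0671), control replicate 1 (0.34, adjusted p = 0.0541) or Apex shaded replicate 1 (0.41, adjusted p = 0.051).

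N starvation against control in Capitol asked the same of the N-inefficient cultivar. Antenna probes averaged −1.22 ± 0.26 relative to control (SD, n = 3), Rubisco small subunit probes −1.84 ± 0.14 and NAC probes 0.86 ± 0.22. The Rubisco class fell (median −1.97; camera adjusted p = 3.52e-09, and adjusted p = 0.585 with an estimated correlation), with 3 of 10 probes called and 10 when adjusted over the list alone. The antenna class fell by 1.23 (adjusted p = 3.52e-09, and adjusted p = 0.585 estimated), with 2 of 15 probes called and 12 over the list alone. NAC probes rose by a median of 0.85 (adjusted p = 0.0153, and adjusted p = 0.897 estimated). All 6 probes of ubiquitin-conjugating enzymes were higher, with a median of 0.44 (adjusted p = 0.0242, and adjusted p = 0.897 estimated). The same cytochrome P450 probe as in Apex rose by 7.14 (SE 0.81, adjusted p = 9.66e-05), a size that is uncertain because 2 of 3 control arrays lay above background, and the same NAC probe by 1.87 (SE 0.45, adjusted p = 0.0289).

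Across all probes for N starvation against control in Capitol, 816 rose and 972 fell, 1788 in all. Probes BrsNa0609979 and BrsNa0149128 rose, with 1 of 3 and 2 of 3 control arrays above background. BrsNa0035626 fell, with 1 of 3 N-starved arrays above background, and BrsNa0163873 was at least 114-fold lower. Within the slide that held both groups, antenna probes differed by −1.30, Rubisco probes by −1.86 and NAC probes by 0.92. The slide block gave 232 calls, not including the NAC probe (1.39 with the block), and the class medians were −1.33 (adjusted p = 7e-08), −1.76 (adjusted p = 4.22e-06) and 0.76 (adjusted p = 0.00233). The count was 356, 574 and 656 without N-starved replicate 1, 2 or 3, 440 without control replicate 2, 586 without control replicate 3, and 5594 without Apex shaded replicate 1. The NAC call ended without control replicate 3 (0.57, adjusted p = 0.0665). The call for ubiquitin-conjugating enzymes ended without N-starved replicate 3 (0.36, adjusted p = 0.052), control replicate 1 (0.38, adjusted p = 0.0725) or Apex shaded replicate 1 (0.44, adjusted p = 0.051).

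**Figure D2:**
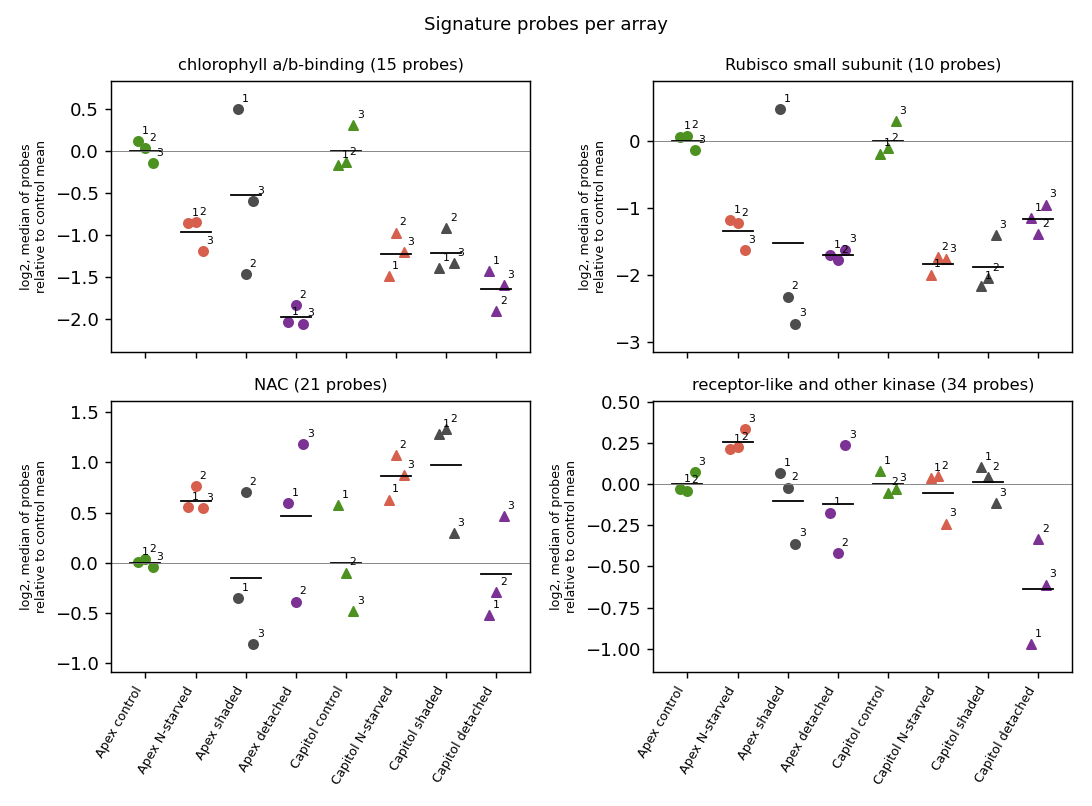
Median log2 signal of the probes of 4 signature classes in each array, relative to the mean of the controls of the same cultivar; points are arrays with their replicate number and lines are group means (n = 3). Rubisco small subunit probes averaged −1.35 in N-starved Apex and −1.84 in N-starved Capitol leaves.

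The responses to N starvation resembled each other in both cultivars, which share no array. Their log2 changes correlated across probes with r = 0.807, against 0.00143 for simulated unchanged groups, which hold independent probes and no slides. The cultivars shared 403 risen and 575 fallen probes, where independent lists of these sizes would share 12.4 and 22.7, and 0 probes changed in opposite directions. Some N-starved arrays of the cultivars shared slides. Apex replicate 1 and Capitol replicate 2 lay on slide 4, and Apex replicate 2 and Capitol replicate 1 on slide 5, which held no control. An effect of these slides could enter both responses, and r and the shared counts make no allowance for it. The test of the difference, Capitol minus Apex, called 0 probes with limma, and 452 had an unadjusted p under 0.05; without Apex control replicate 1 it called 1. Antenna probes fell more in Capitol, by a median of −0.35 (camera adjusted p = 0.00682, and adjusted p = 0.682 with an estimated correlation). This call ended without Apex control replicate 3 (−0.28, adjusted p = 0.057), Capitol N-starved replicate 1 (−0.20, adjusted p = 0.206) or Capitol control replicate 3 (−0.19, adjusted p = 0.257). In control leaves antenna probes stood higher in Capitol by a median of 0.25 relative to all probes, which was not called. The difference in response is therefore no difference of that size between the N-starved leaves.

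Shading against control in Apex asked what shading of the leaf changed. Rubisco small subunit probes averaged −1.53 ± 1.75 relative to control (SD, n = 3): replicate 1 stood at 0.48, above every control, and the others far below. Antenna probes averaged −0.52 ± 0.98. The Rubisco class fell by a median of 1.59 (camera adjusted p = 1.02e-05, and adjusted p = 0.869 with an estimated correlation), with 0 of 10 probes called over all probes and 8 over the list alone. Ubiquitin probes fell by 0.47 (adjusted p = 2.14e-05, and adjusted p = 0.897 estimated), cytochrome P450 probes by 0.67 (adjusted p = 0.00467, and adjusted p = 0.67 estimated) and probes of papain-like cysteine proteases by 0.73 (adjusted p = 0.0489, and adjusted p = 0.897 estimated). Per array these 3 averaged −0.40 ± 0.29, −1.26 ± 1.36 and −0.79 ± 1.17, the last with replicates on both sides of the control mean. Across all probes 9 rose and 6 fell. BrsNa0134698 was at least 3.18-fold higher and BrsNa0010648 rose by 2.45, whereas BrsNa0118349 fell by 3.55 and BrsNa0290192 fell by 3.33.

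Without Apex shaded replicate 1, shading in Apex changed 12392 probes, 5587 up and 6805 down, including all 15. This rests on shaded replicates 2 and 3. Replicate 2 had a cultivar score of 0.46, between Apex at 0 and Capitol at 1, and lay on slide 1, which held no control. Replicate 3 was the second dimmest of the 24 arrays. All 4 named probes were called again, BrsNa0010648 with 2.85, BrsNa0118349 with −4.19 and BrsNa0290192 with −4.11. Rubisco probes then fell by 2.63 (adjusted p = 1.12e-10), with all 10 called, antenna probes by 0.94 (adjusted p = 0.000624), with 8 called, cytochrome P450 probes by 1.02 (adjusted p = 0.0127) and ubiquitin probes by 0.41 (adjusted p = 0.0448). These class tests are camera with the preset correlation. Neither an estimated correlation nor fry was run for this fit. The papain-like class was then not called (−0.91, adjusted p = 0.246), nor was it without control replicate 2 (−0.69, adjusted p = 0.132) or shaded replicate 3 (−0.13, adjusted p = 0.477). The P450 call ended without shaded replicate 3 (−0.30, adjusted p = 0.0643). The count was 2, 1 and 1 without control replicate 1, 2 or 3, and 3 without shaded replicate 2. Within slide 2, which held replicate 1, Rubisco probes differed by 0.46 and antenna probes by 0.41. Within slide 4, which held replicate 3, they differed by −2.68 and −0.43. Ubiquitin probes differed by −0.32 and −0.81 within these slides and cytochrome P450 probes by 0.15 and −1.41. With the slide as a block 1 probe was called, which was none of the 4 named, and the Rubisco median was −1.43 (adjusted p = 0.000693).

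Shading against control in Capitol raised the median of all probes by 0.20 (0.04 under quantile normalization, 0.0883 without Capitol shaded replicate 2), so class values relative to this shift are given as well. Antenna probes averaged −1.21 ± 0.26 relative to control (SD, n = 3), Rubisco small subunit probes −1.88 ± 0.41 and NAC probes 0.97 ± 0.59. The lowest shaded array stood at 0.30 for NAC probes, within the range of the controls (−0.48 to 0.58). The Rubisco class fell by a median of 1.99 (−2.19 relative to all probes; camera adjusted p = 3.52e-09, and adjusted p = 0.585 with an estimated correlation), with 9 of 10 probes called. The antenna class fell by 1.17 (−1.37 relative to all probes; adjusted p = 5.15e-09, and adjusted p = 0.585 estimated), with 4 of 15 called, but was not called under quantile normalization (−0.23, adjusted p = 0.222). NAC probes rose by 1.32 (1.1 relative to all probes; adjusted p = 0.000953, and adjusted p = 0.897 estimated), with 20 of 21 above control, 2 called and 10 over the list alone. Probes of RNA-binding RRM proteins rose by 0.99 (0.80 relative to all probes; adjusted p = 0.0107, and adjusted p = 0.897 estimated). Ubiquitin probes fell by 0.23 (−0.42 relative to all probes; adjusted p = 0.0107, and adjusted p = 0.897 estimated), a direction that turned to 0.44 under quantile normalization. Per array the RRM and ubiquitin classes averaged 1.42 ± 0.05 and −0.22 ± 0.20. A C2H2 zinc finger probe with QALGGH rose by 2.26 (SE 0.48, adjusted p = 0.0163), and an antenna probe with HLSDPFGNN fell by 2.67 (SE 0.64, adjusted p = 0.0268).

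Across all probes for shading against control in Capitol, 1588 rose and 1583 fell, a share of 50.1% up that was 38.4% under quantile normalization. BrsNa0517719 rose, with 1 of 3 control arrays above background, and BrsNa0194834 rose, with 0 of 3 control arrays above background. BrsNa0159623 fell by 9.58 and BrsNa0215054 fell by 9.53. Capitol shaded replicates 1 and 2 lay on slide 1, which held no control. Within the slide that held both groups, antenna probes differed by −0.99, Rubisco probes by −1.35, RRM probes by 0.89, ubiquitin probes by −0.31 and NAC probes by 0.03. The only control on that slide was Capitol control replicate 1, which lay nearer to the treated arrays on component 1 than the other Capitol controls. A fit with the slide block called 0 probes with limma, against 3171 without it; 5346 then had an unadjusted p under 0.05, against 13718 without it. None of the single probes named here was called with that block. The antenna median was then −0.90 (adjusted p = 9.77e-05) and the Rubisco median −1.51 (adjusted p = 1.15e-05), but the NAC class was not called (0.31, adjusted p = 0.493). With the scan as a block neither the NAC class (0.38, adjusted p = 0.288) nor the RRM class (0.75, adjusted p = 0.0978) was called. The count was 2085, 281 and 584 without control replicate 1, 2 or 3, 546 and 680 without shaded replicate 1 or 2, and 9546 without Apex shaded replicate 1. The ubiquitin call ended without control replicate 3 (−0.11, adjusted p = 0.132) or shaded replicate 2 (−0.18, adjusted p = 0.118).

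The shading responses of the cultivars correlated with r = 0.560 across probes, a value that makes no allowance for the slide. Apex shaded replicate 2 and Capitol shaded replicates 1 and 2 shared slide 1, which held no control, so an effect of that slide could enter both responses. The cultivar score of 0.46 of Apex shaded replicate 2 also leaves uncertain what the correlation says about the cultivars, the more so without Apex shaded replicate 1. Limma called 0 probes as different between cultivars with or without that array, and 4442 or 6376 had an unadjusted p under 0.05. Without Apex shaded replicate 2 it called 59, without Apex shaded replicate 3 it called 4, without Capitol shaded replicate 3 it called 10, and without Apex control replicate 1 or Capitol shaded replicate 1 it called 1. The median of all probes differed by 0.20 (0.00 under quantile normalization). The response of NAC probes, Capitol minus Apex, differed by a median of 1.05 (0.84 relative to all probes; camera adjusted p = 0.00116, and adjusted p = 0.682 with an estimated correlation). This call ended without Apex shaded replicate 1 (0.89, adjusted p = 0.0623) and with the slide as a block (0.39, adjusted p = 0.0863).

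Detachment against control in Apex asked what cutting the leaf from the plant changed. Antenna probes averaged −1.97 ± 0.12 relative to control (SD, n = 3) and Rubisco small subunit probes −1.71 ± 0.08. The antenna class fell by a median of 1.88 (camera adjusted p = 3.52e-09, and adjusted p = 0.585 with an estimated correlation), with 12 of 15 probes called and 14 over the list alone. The Rubisco class fell by 1.84 (adjusted p = 8.61e-05, and adjusted p = 0.897 estimated), with 7 of 10 called and 9 over the list alone. WRKY probes rose by 0.66 (adjusted p = 0.0166, and adjusted p = 0.897 estimated), with 3 of 16 called, and kinase probes fell by 0.35 (adjusted p = 0.0445, and adjusted p = 0.897 estimated), with 5 of 34 called. Ubiquitin probes fell by 0.35 (adjusted p = 0.0235, and adjusted p = 0.922 estimated), a direction that turned to 0.15 under quantile normalization. Per array these 3 classes averaged 0.21 ± 0.51, −0.12 ± 0.33 and −0.16 ± 0.50, with replicates on both sides of the control mean. The cytochrome P450 probe with PLSFRPERF rose by 7.15 (SE 0.81, adjusted p = 3.37e-05). EF-hand probes, from calcium-binding proteins, went both ways: DLDGNGRISAKEL rose by 2.79 (SE 0.44, adjusted p = 0.000478) and DKNGDGFITLDEL fell by 5.07 (SE 0.71, adjusted p = 0.000168).

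Across all probes for detachment against control in Apex, 3937 rose and 4122 fell. BrsNa0429505 was at least 344-fold and BrsNa0101049 at least 189-fold higher, and BrsNa0007101 was at least 225-fold and BrsNa0109028 at least 142-fold lower. Within the slide that held both groups, antenna probes differed by −1.81, Rubisco probes by −1.95, WRKY probes by 0.49, kinase probes by −0.63 and ubiquitin probes by −0.47. With the slide as a block 4393 probes were called, and the medians were −1.68 for antenna (adjusted p = 2.5e-06), −1.85 for Rubisco (adjusted p = 0.000693) and, no longer called, 0.39 for WRKY (adjusted p = 0.0528). The scan block ended the WRKY call as well (0.48, adjusted p = 0.0552). The total of 8059 was 4761 without control replicate 1, 5114 without control replicate 3, 5271 without detached replicate 1 and 11439 without Apex shaded replicate 1. The WRKY call ended without detached replicate 3 (0.55, adjusted p = 0.123). The kinase call ended without control replicate 1 (−0.34, adjusted p = 0.0612), control replicate 3 (−0.33, adjusted p = 0.0747), detached replicate 1 (−0.41, adjusted p = 0.0518), detached replicate 2 (−0.16, adjusted p = 0.17) or Apex shaded replicate 1 (−0.35, adjusted p = 0.0626). The ubiquitin call ended without control replicate 2 (−0.25, adjusted p = 0.233), detached replicate 2 (−0.22, adjusted p = 0.189), detached replicate 3 (−0.29, adjusted p = 0.0865) or Apex shaded replicate 1 (−0.35, adjusted p = 0.0522).

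Detachment against control in Capitol asked the same of the other cultivar. Antenna probes averaged −1.64 ± 0.24 relative to control (SD, n = 3), Rubisco small subunit probes −1.16 ± 0.22 and kinase probes −0.64 ± 0.32. The antenna class fell by a median of 1.7 (camera adjusted p = 6.56e-08, and adjusted p = 0.62 with an estimated correlation), with 8 of 15 probes called. The kinase class fell by 0.78 (adjusted p = 3.74e-07, and adjusted p = 0.478 estimated), with 9 of 34 called and 15 over the list alone. The Rubisco class fell by 1.28 (adjusted p = 0.00604, and adjusted p = 0.897 estimated), with 0 of 10 called by limma. The P450 probe with PLSFRPERF rose by 7.73 (SE 0.81, adjusted p = 2.8e-05, 2 of 3 control arrays above background), and an antenna probe with ELKNGRLAM fell by 3.30 (SE 0.70, adjusted p = 0.00606). The EF-hand probes moved as in Apex, by 1.47 (SE 0.44, adjusted p = 0.0438) and −3.18 (SE 0.71, adjusted p = 0.00811).

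Across all probes for detachment against control in Capitol, 2288 rose and 2362 fell. BrsNa0517719 and BrsNa0101049 rose, each with 1 of 3 control arrays above background. BrsNa0054213 was at least 101.3-fold lower, with 0 of 3 detached arrays above background, and BrsNa0215054 fell by 7.59. No slide held both groups, so no value within a slide could be had. The slide block gave 970 calls, not including BrsNa0517719, the ELKNGRLAM probe (−4.37 with the block) or the EF-hand probes (0.77 and −3.17 with the block), and the medians were −2.15 for antenna (adjusted p = 2.5e-06), −1.43 for Rubisco (adjusted p = 0.0172) and −0.88 for kinases (adjusted p = 1.15e-05). The total of 4650 was 2076 and 1842 without control replicate 2 or 3, 2422 and 2631 without detached replicate 1 or 2, and 8098 without Apex shaded replicate 1.

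The detachment responses correlated across probes with r = 0.720. Apex detached replicate 2 had a cultivar score of 0.23, off the level of Apex at 0, which limits what the correlation says about the cultivars. It shared slide 2 with Capitol detached replicates 1 and 3, and Apex detached replicate 3 shared slide 5 with Capitol detached replicate 2. An effect of these slides could enter both responses, and neither r nor the shared counts make an allowance for it. Of 8059 probes called in Apex and 4650 in Capitol, 3034 changed in the same direction in both, 1528 up and 1506 down (181 and 195 for independent lists), and 3 changed in opposite directions. Limma called 0 probes as different between cultivars and 2791 had an unadjusted p under 0.05; it called 3 without Apex detached replicate 2 and 2 without Apex detached replicate 3. The response of WRKY probes, Capitol minus Apex, differed by a median of −0.89 (camera adjusted p = 6.4e-05, and adjusted p = 0.682 with an estimated correlation). With the preset correlation the call also held with each array of the compared groups left out in turn, but fry did not make it (adjusted p = 0.305). In control leaves WRKY probes stood higher in Capitol by a median of 0.51, which was not called (adjusted p = 0.112), so the difference in response is no difference of that size between the detached leaves.

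**Figure D3:**
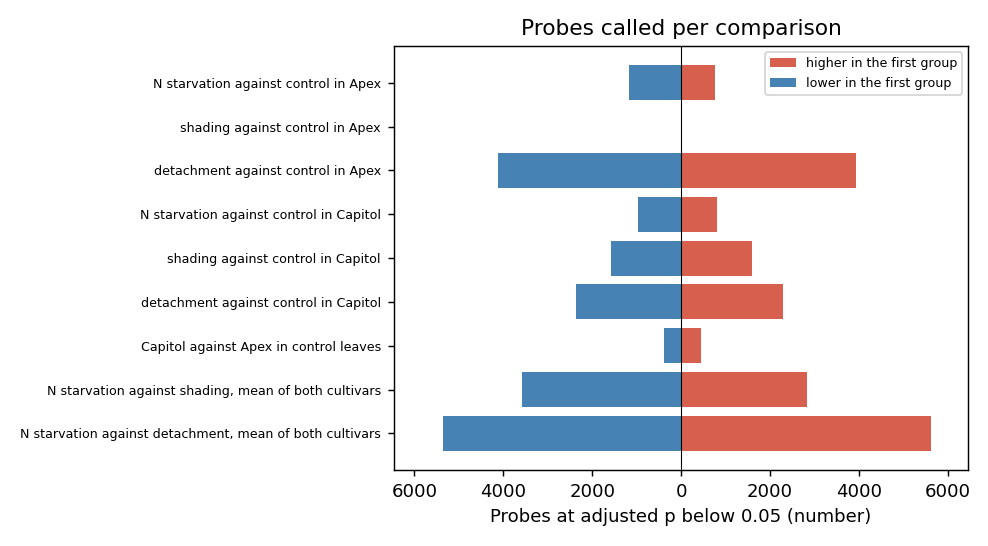
Number of probes (horizontal) higher (right) and lower (left) in the first group named, for 9 comparisons, at an adjusted p below 0.05 in limma. Shading against control in Apex gave 15 with all arrays and 12392 without Apex shaded replicate 1.

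Capitol against Apex in control leaves compared the cultivars without treatment: 460 probes were higher in Capitol and 378 lower. None of the 15 signature classes differed by the camera test. BrsNa0956989 and BrsNa0031477 were higher, each with 1 of 3 Apex arrays above background. BrsNa0249937 and BrsNa0252577 were lower in Capitol, where 0 of 3 arrays measured them. No slide held both groups. The total was 838, and 25 with the slide as a block, of the 4 probes named only BrsNa0249937 among them. It was 463, 408 and 447 without Apex control replicate 1, 2 or 3, 461, 430 and 510 without Capitol control replicate 1, 2 or 3, and 1295 without Apex shaded replicate 1. A score over 179 probes that differed by more than 4 on the log2 scale between the N-starved cultivars placed most arrays with their cultivar (0 for Apex, 1 for Capitol). Apex shaded replicate 2 stood at 0.46, Apex detached replicate 2 at 0.23 and Apex shaded replicate 1 at 0.07. The lowest Capitol array was shaded replicate 2 at 0.86.

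**Figure D4:**
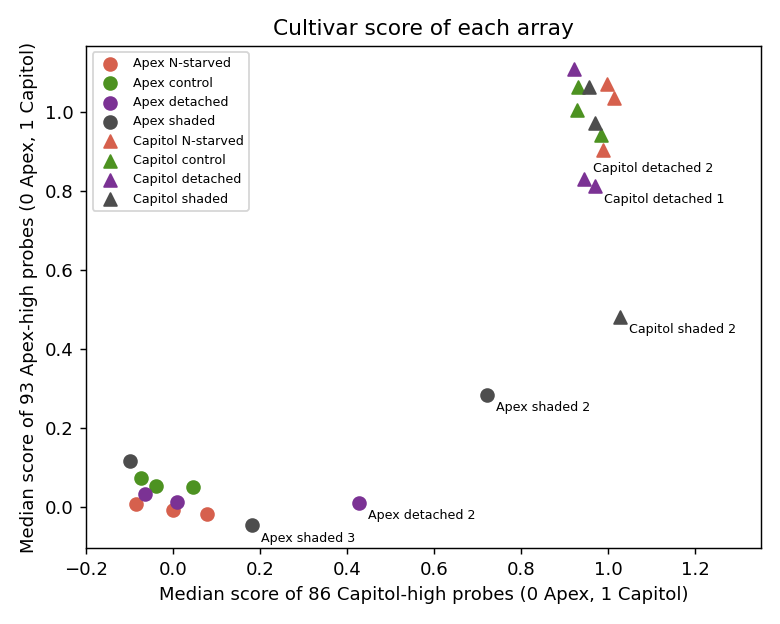
Median cultivar score of each array over 86 probes high in Capitol (horizontal) and 93 probes high in Apex (vertical), where 0 is the level of N-starved Apex and 1 that of N-starved Capitol leaves; each point is 1 array. Apex shaded replicate 2 lies between the cultivars on both axes, at 0.72 and 0.29.

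N starvation against shading, taken as the mean of both cultivars, set the N response against that to shading with no control array in the contrast: 2846 probes were higher with N starvation and 3588 lower, a share of 44.2% up that was 55.2% under quantile normalization. Ubiquitin probes were higher by a median of 0.32 (camera adjusted p = 7.17e-05, and adjusted p = 0.91 with an estimated correlation), with 21 of 23 positive and 5 called; with the slide as a block the median was 0.54. The P450 probe with PLSFRPERF was higher by 4.13 (SE 0.58, adjusted p = 0.000171, 4 of 6 shaded arrays above background), and a C2H2 zinc finger probe with QALGGH was lower by −1.47 (SE 0.34, adjusted p = 0.00828). BrsNa0149128 and BrsNa0134559 were higher, with 3 of 6 and 4 of 6 shaded arrays above background. BrsNa0035626 was lower, with 1 of 6 N-starved arrays above background, and BrsNa0243950 was lower by −6.61. With the slide as a block 2307 probes were called, not including the QALGGH probe. The total of 6434 was 12138 without Apex shaded replicate 1 and 4123 without Capitol N-starved replicate 1.

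N starvation against detachment, also over both cultivars, gave 5627 higher and 5351 lower probes, and the median of all probes moved by 0.10 (−0.05 with normexp background correction). Kinase probes were higher with N starvation by a median of 0.64, or 0.54 relative to all probes (camera adjusted p = 3.03e-05, and adjusted p = 0.482 with an estimated correlation), with 31 of 34 positive and 13 called. The EF-hand probe with DKNGDGFITLDEL was higher by 3.45 (SE 0.50, adjusted p = 9.78e-05) and that with DLDGNGRISAKEL lower by −2.20 (SE 0.31, adjusted p = 8.56e-05). A NAC probe with WVLCRIY was higher by 1.79 (SE 0.32, adjusted p = 0.000642), and a WRKY probe with TYEGEHNH was lower by −2.14 (SE 0.42, adjusted p = 0.00151). BrsNa0625651 was higher, with 1 of 6 detached arrays above background, and BrsNa0599497 was higher by 5.48. BrsNa0078761 and BrsNa0429505 were lower, each with 1 of 6 N-starved arrays above background. The slide block gave 6902 calls, and the kinase median was 0.66. Leaving out 1 array of the compared groups gave between 8144 and 11507 calls, and leaving out Apex shaded replicate 1 gave 14288.

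The responses to the inducers within a cultivar share its 3 control arrays, which alone gave simulated unchanged groups a correlation of about 0.50 and a covariance of 0.165. In Apex, N starvation and shading correlated with r = 0.54 (covariance 0.357), N starvation and detachment with r = 0.55 (0.591), and shading and detachment with r = 0.50 (0.501). In Capitol the values were 0.56 (0.460), 0.51 (0.416) and 0.46 (0.453). The covariances exceeded the simulated ones by 0.192 to 0.425. Without Apex shaded replicate 1 the Apex correlations that involve shading were 0.588 with N starvation and 0.540 with detachment. The simulated 0.50 does not apply to this smaller shaded group, and no simulated value was computed for it. In Apex, N starvation and detachment shared 435 rises and 623 falls (59.9 and 96.5 for independent lists), with 28 opposite changes. In Capitol, N starvation and shading shared 162 and 232 (25.98 and 30.9), with 11 opposite. N starvation and detachment shared 663 in Capitol, 309 of them up, where 37.4 up and 46.03 down would be shared by independent lists, with 25 opposite. Shading and detachment shared 304 and 384 (72.9 and 74.97), with 41 opposite. Part of the excess may come from the shared controls. In a test added after the data had been seen, the controls were split so that each pair shared no array. The mean covariance over 6 splits was then 0.284, 0.517 and 0.427 in Apex and 0.356, 0.313 and 0.349 in Capitol, in the order above, and the lowest of any split was 0.0940. Simulated unchanged groups lay between −0.00836 and 0.00830, a range that is narrow because their probes were independent. Correlations fell to between 0.322 and 0.443, and in Capitol a split called up to 194 probes in opposite directions. Comparisons of different inducers across the cultivars share no array, but some of their arrays share slides, for which the simulations make no allowance. N starvation in Apex and detachment in Capitol shared 226 rises and 281 falls (34.8 and 55.3), with 48 opposite and a covariance of 0.360 against 0.000282 simulated. Detachment in Apex and N starvation in Capitol shared 383 and 490 (64.4 and 80.3), with 40 opposite and a covariance of 0.446 against 8.58e-05. N starvation in Apex and shading in Capitol shared 259 in the same direction, where 24.2 up and 37.0 down would be shared by independent lists, with 30 opposite and a covariance of 0.411 against 0.000536. Detachment in Apex and shading in Capitol shared 315 and 466 (125 and 131), with 118 opposite and a covariance of 0.491 against 0.000852. All 3 inducers changed 199 probes in the same direction in Capitol, 94 of them up, of 7994 called with any inducer, and 69 were called up with one and down with another. Independent lists would share 1.2 up and 1.5 down, but the comparisons share their controls. With 1 control per inducer, which leaves less power, at most 1 probe was shared by all 3 in Capitol, so the part due to the shared controls stays open. In Apex they raised 1 and lowered 2, of 8904, and 31 were called both ways. Across both cultivars, 40 probes rose and 57 fell in all comparisons with control other than shading in Apex, which share controls within a cultivar. Leaving out Apex shaded replicate 1 raised the probes shared by N starvation and shading in Apex from 4 to 3478. Both lists were much longer in that fit and share their controls, and no expected value was computed for it. The array was also singled out partly because it did not follow the shading response.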

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

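The results below are classes whose response differed between the cultivars by a test of the difference itself (Capitol minus Apex, camera with a preset correlation). With an estimated correlation all of them had adjusted p = 0.682, and the lowest adjusted p with fry was 0.305. The classes, and the test of a mixture below, were chosen after the data or the result had been seen. Groups of 3 were not tested for outlying samples.

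For N starvation, chlorophyll a/b-binding probes differed by −0.35 (adjusted p = 0.00682), Rubisco small subunit probes by −0.45 (adjusted p = 0.0136) and WRKY probes by −0.37 (adjusted p = 0.0277). Cytochrome P450 probes differed by 0.24 (adjusted p = 0.000144), with 10 of 15 positive and a mean of 1.02. The antenna call ended without Apex control replicate 3 (−0.28), Capitol N-starved replicate 1 (−0.20) or Capitol control replicate 3 (−0.19). The Rubisco call ended without Apex N-starved replicate 1 (−0.35), Apex control replicate 3 (−0.37), Capitol N-starved replicate 1 (−0.37) or Capitol control replicate 3 (−0.33). The WRKY call ended without Apex N-starved replicate 1 (−0.25), Capitol N-starved replicate 3 (−0.20) or Capitol control replicate 1 (−0.13), and with the scan as a block (−0.28, adjusted p = 0.0882). With the preset correlation the P450 call survived leaving out each array of the compared groups, but fry did not make it (adjusted p = 0.368). The P450 call ended when only probes above background on all arrays were used (0.18, adjusted p = 0.327). In control leaves the Capitol minus Apex medians, relative to all probes, were 0.25 for antenna, 0.22 for Rubisco, 0.51 for WRKY and −0.35 for P450 probes, none of them called. The differences in response are therefore no differences of that size between the N-starved leaves.

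For shading, antenna probes differed by −0.67 (adjusted p = 6.03e-05) and Rubisco probes by −0.47 (adjusted p = 0.017), and both directions turned under quantile normalization, to 0.26 and 0.38. Papain-like protease probes differed by 1.08 (adjusted p = 0.00696), NAC probes by 1.05 (adjusted p = 0.00116), P450 probes by 0.67 (adjusted p = 0.0258), C2H2 zinc finger probes by 1.13 (adjusted p = 0.0125), small GTPase probes by 0.87 (adjusted p = 0.0429) and RRM probes by 1.14 (adjusted p = 0.00166). EF-hand probes differed by −0.28 (adjusted p = 0.0429). Without Apex shaded replicate 1 the values were −0.06 for antenna, 0.57 for Rubisco, 0.89 for NAC, 1.1 for C2H2, −0.24 for EF-hand, 0.86 for small GTPase and 0.83 for RRM probes, and none of these 7 was called. Without Apex shaded replicate 3 the calls for papain-like (0.51), P450 (0.17), C2H2 (0.72) and small GTPase probes (0.45) ended. With the slide as a block the calls for Rubisco (−0.19), NAC (0.39) and C2H2 probes (0.83) ended, and with the scan as a block those for Rubisco (−0.14), C2H2 (0.97) and small GTPase probes (0.46). The small GTPase call also ended with the replicate block (0.87, adjusted p = 0.0519). The Rubisco call ended without Capitol shaded replicate 2 (−0.35), and the P450 call without Apex control replicate 2 (0.52) or Capitol control replicate 1 (0.49). The EF-hand call ended without Apex control 1 (−0.31) or 3 (−0.26), Apex shaded 2 (−0.24), Capitol control 1 (−0.28) or Capitol shaded 1 (−0.26) or 3 (−0.31). The small GTPase call ended without Apex control 1 (0.78) or 2 (0.80), Capitol control 1 (0.84) or 3 (0.78), or Capitol shaded 1 (0.66) or 3 (0.92).

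For detachment, ubiquitin probes differed by 0.22 (adjusted p = 0.0141), WRKY probes by −0.89 (adjusted p = 6.4e-05), kinase probes by −0.36 (adjusted p = 0.00492) and P450 probes by 0.58 (adjusted p = 0.00417). With the preset correlation the WRKY and P450 calls survived leaving out each array of the compared groups, but fry called neither (adjusted p = 0.305 and 0.333). The kinase call ended without Apex detached replicate 3 (−0.26). The ubiquitin call ended without Apex control 2 (0.12), Apex detached 2 (0.10) or 3 (0.22), or Capitol control 2 (0.12).

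Exchanging the cultivar labels within treatments tested whether these differences, counted as probes at an unadjusted p under 0.05, exceed those of other splits. For N starvation 452 such probes were found, and 38 of 100 splits gave as many (highest other 2241). For shading there were 4442, with 37 of 100 (highest 10553), and for detachment 2791, with 12 of 100 (highest 7593). Chance could not be excluded for any of the 3.

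Apex shaded replicate 1 lay nearer to the Apex controls than to the other shaded Apex arrays, a sample far from the others of its group. Its slope on the Capitol shading response was −0.157, where the controls ranged from −0.03 to 0.02. A swap of 2 arrays within the series was argued against, because the highest slope of an Apex control array was 0.0238. A leaf that was shaded but responded little was argued against as well, because its Rubisco small subunit median was 0.477 and its antenna median 0.50, above the control ranges of −0.14 to 0.08 and −0.15 to 0.12. An unshaded Apex leaf under a shaded label stays open and cannot be told apart from other causes, because its slope lay below the range of the controls and no record of the leaf exists in the files.

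Apex shaded replicate 2 had a cultivar score of 0.46, between Apex and Capitol. Capitol RNA or labelled cRNA mixed into the sample was argued against, because 35.5% of the probes high in Apex stood near the Capitol level (a score over 0.75), against at most 2.15% in the other Apex arrays; a mixture would hardly lower such probes. A plant carrying alleles of both cultivars at separate loci may explain the score, since 82.0% of the cultivar probes lay near one or the other level. The 3 shaded Apex arrays lay at 81.6% to 82.1% on that measure, so it does not set this array apart by itself.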

How the results depend on the processing

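Chosen after seeing the data were the scan block, the array weights, the split controls, the fits without 3 doubted arrays or without Apex shaded replicate 1, and the classes with their slide block. Of the counts of calls under alternatives other than leaving out 1 array, 120 stayed within 1.5 times and 45 did not; the cause was not tested for any of the values below, except that fits with fewer arrays or probes differ in size. Each is a count of probes called. With the slide as a block the counts were 957 (N starvation in Apex), 1 (shading in Apex), 4393 (detachment in Apex), 232 (N starvation in Capitol), 0 (shading in Capitol), 970 (detachment in Capitol), 25 (cultivars), 2307 (N starvation against shading) and 6902 (against detachment). With array weights, which gave Apex shaded replicate 1 a weight of 0.118, they were 13519 and 3336 (N starvation and shading in Apex), 22792, 16595 and 23137 (N starvation, shading and detachment in Capitol), 35 and 90 (cultivar differences with N starvation and detachment), 4447 (cultivars), 10489 and 20083 (N starvation against shading and detachment). Leaving out Apex shaded replicate 1 gave 5772 and 5594 (N starvation in Apex and Capitol), 9546 (shading in Capitol), 8098 (detachment in Capitol) and 1295 (cultivars). With only the compared groups they were 7111 and 7431 (N starvation), 0 (shading in Apex), 2 and 1 (cultivar differences with N starvation and detachment), 1289 (cultivars) and 3002 (N starvation against shading). Without the 3 doubted arrays they were 25 and 934 (shading in Apex and Capitol) and 7 (its cultivar difference). Shading gave 1 and 1966 without a filter, 1 and 47 with the scan as a block, 9 with the authors' matrix (Apex) and 4805 with quantile normalization (Capitol). Normexp gave 3 for the cultivar difference with detachment, probes above background on all arrays gave 446 between cultivars, and the 2-fold criterion gave 3339 and 5700 for N starvation against shading and detachment.

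Replicate numbers did not pair the samples: 20 of 84 pairs with the same number had deviations correlated over 0.1 (median −0.0144), against 38 of 168 with different numbers, and 9 of 24 arrays were closest to their own number. With the replicate block shading in Apex gave 1 call; the other counts stayed within 1.5 times.

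Leaving out 1 array of the compared groups gave 491 to 1064 (N starvation in Apex), 1 to 12392 (shading in Apex), 4761 to 8259 (detachment in Apex), 356 to 1794, 281 to 3224 and 1842 to 5038 (the same in Capitol), 0 to 1, 0 to 59 and 0 to 3 (cultivar differences), 408 to 510 (cultivars), 4123 to 12138 and 8144 to 11507 (N starvation against shading and detachment). Where a group kept 2 arrays, the pooled spread was used. Without Apex shaded replicate 1 the shared calls were 3478, 3706 and 5150 within Apex, 2994, 2743 and 3108 within Capitol, and 3861, 5744 and 5672 between cultivars for N starvation, shading and detachment; quantile normalization gave 10 for shading between cultivars. That array was singled out partly because it did not follow the Capitol shading response, so that choice may raise the 5744 and the other counts that involve shading in Apex. With the controls split between the inducers the correlations in Capitol moved to 0.379 (N starvation and shading), 0.336 (N starvation and detachment) and 0.322 (shading and detachment), where fewer controls add noise as well.

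For 44 class results, alternatives other than leaving out 1 array of the compared groups were counted first. Of these, 337 kept the call, 128 lost it and 5 turned its direction. Quantile normalization turned ubiquitin (0.15 with detachment in Apex, 0.44 with shading in Capitol). It also turned the cultivar difference with shading for antenna (0.26) and Rubisco probes (0.38). Leaving out the 3 doubted arrays turned that difference for P450 probes (−0.12). Leaving out 1 array of the compared groups kept 317 calls, lost 60 and turned 1. It moved the Rubisco value of the cultivar difference with shading between −0.99 and 0.57, the positive end without Apex shaded replicate 1. The estimated correlation ended all 44, fry 36, the filter on all arrays 10, the scan block 8 and normexp 7. The slide block, quantile normalization and leaving out the 3 doubted arrays ended 6 each, and the replicate block 1. Leaving out Apex shaded replicate 1 ended 4 results of comparisons that do not hold this array. Among results of comparisons that hold it, leaving it out ended 7 and turned the direction of 1. For 109 named probe results 1173 alternatives other than leaving out 1 array kept the call and 174 lost it; the slide block alone ended 54 of the 109 and the scan block 25, in no case with a turned direction. Gene lists on all probes of a gene and the matrix on the same probes were not run, because nothing pairs their names. Signal over background limits dim probes most, since 37005 of 49874 tested probes were above background on all arrays.

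Splits of 3 against 3 arrays number 10, too few for a share under 0.05. The real split gave as many calls as 1 of 10 splits (itself) in each comparison but shading in Apex: 1926 with the highest other at 1 (N starvation in Apex), 8059 and 0 (detachment in Apex), 1788 and 0, 3171 and 9, 4650 and 0 (the same inducers in Capitol, shading second) and 838 and 0 (cultivars). Shading in Apex gave 15, and 4 of 10 splits gave as many; the highest, 4707, set shaded replicate 1 with controls 1 and 3, which points to a structure of the samples. For N starvation against shading (6434, highest other 5716) and against detachment (10978, highest 726), 1 of 100 splits, the real one, gave as many. That share is under 0.05, so counts this high were rare among the splits run. These 100 were drawn from a larger number of splits and make no allowance for the slide, so chance was not excluded outright.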

Other observations

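Signatures with fewer than 5 probes were not tested as classes; 23 of them held 46 tested probes, and the items named here were chosen after their values were seen. A probe with a chalcone synthase signature, an enzyme of flavonoid synthesis, rose by 5.27 with N starvation in Capitol and by 5.52 and 4.53 with detachment in Apex and Capitol. It was not called with N starvation in Apex (3.37) or with shading (0.96 and 3.65). Of 4 ATG8 probes, from a protein of autophagy, 3 rose with N starvation in Capitol, where all 4 lay between 0.87 and 1.24, and 0 were called in Apex (0.51 to 0.80); the difference was not tested for them. Of 3 expansin probes 2 fell with shading in Capitol (−4.86 to −2.76), calls that ended with the slide as a block, where 0 probes were called. A PR-1 type probe fell by 3.64 with N starvation and fell by 3.88 with shading in Capitol, and the shading call ended with that block as well. For the other calls named in this section no value with the slide block is given.

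Detachment moved others. Of 2 class III peroxidase probes 1 rose, by 3.31 in Apex and 6.25 in Capitol. Of 4 sugar transporter probes 1 rose and 2 fell in Apex (−6.38 to 3.62), and 2 fell in Capitol. Of 3 core histone probes 2 rose in Apex and 1 in Capitol, and of 3 metallothionein probes 1 rose in Capitol (1.62 at most).

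Shading in Capitol raised the median of all probes by 0.20. The raised signal floor of Capitol shaded replicate 2, where 97.9% of the probes were above background, cannot be told apart as a cause, because the median was 0.0883 without that array, neither near 0 nor unchanged. A change confined to dim probes stays open: the brighter 50% of the probes moved by 0.0445 and the dimmer ones by 0.40. No biological explanation was tested.

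Apex detached replicate 2 stood at 0.43 over the probes high in Capitol and at 0.01 over those high in Apex. Capitol shaded replicate 2 stood at 0.48 over the probes high in Apex. Capitol control replicate 1 followed the Apex detachment response with a slope of 0.36, against −0.15 and −0.21 for the other controls.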
